A study of Mus musculus with 3 samples.

How the data were processed

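Single-cell RNA was measured in 3 libraries of wild-type mouse kidney at embryonic day 14.5, from a mixed strain of mostly CD-1 and 129. The platforms were Drop-seq, 10x Chromium and Fluidigm C1, with 1 library each and no replicate library on any platform. In Drop-seq and 10x Chromium each cell is captured in a droplet and its transcripts carry molecular identifiers (UMIs). In Fluidigm C1 each cell is captured in a chamber of a chip, and the C1 values are read counts with no molecular identifier stated. The preparation text in the labels is that of Drop-seq for all 3 samples, so the 10x and C1 protocols are not given in the sources used here. The submitters' processing notes name Bowtie2 2.2.7 for Drop-seq and C1, Cell Ranger 1.3.0 for 10x, and mouse genome build mm10 for all 3. The tool that counted reads per gene in Drop-seq and C1, the annotation and the authors' choice of cells are not given in the sources used here.

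The deposited count tables hold whole-number counts per gene and cell, and these were used for all comparisons. The authors also deposited a normalized table per platform. The Drop-seq and C1 normalized tables hold counts per 10000 of each cell's total, and 25 gene names in the Drop-seq copy had turned into dates. In the 10x normalized table, deposited as CPM per its name, 100% of the 5916745 entries above 0 equalled 10000 times the count over a cell total within a relative tolerance of 1e-06, with the total taken from the cell whose place in the table matched the entry's rank among the gene's cells above 0. Only 0.333% of them matched the cell's own total, and the column sums ran from 2500 to 76871. The normalized tables were used only for an alternative value of Gdnf. The C1 table lists no mitochondrial gene. A deposited list pairs the C1 raw read files with cells. It holds 1580 cells, of which 894 are in the count table, in a pair of name groups (HT, 562 of 820 cells, and E14, 332 of 760 cells) whose meaning is not given in the sources used here.

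Cells were kept with 500 or more detected genes and at most 20% mitochondrial counts, after removal of doublets called by Scrublet in scanpy 1.11.5 with an expected rate of 6%. Where fewer than 0.5% of cells were called, the calls were taken as a failed run and none was removed, which was the case for Drop-seq. Each library was clustered alone in Python 3.11.15 from counts scaled to 10000 per cell, log-transformed, with 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1 (leidenalg 0.10.2, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, seed 1). Genes of the fixed lists and cell cycle, mitochondrial, ribosomal and haemoglobin genes were kept out of the variable genes. Clusters were named from 13 marker lists written beforehand. A cluster took the class with the highest mean marker z score if 3 or more of its markers were in at least 5% of the cluster's cells and above the rest of the library, and if no other class had more markers among the cluster's top 10 genes. A stromal cluster whose top genes held more markers of the other stromal class took no zone, and a class needed 20 cells to enter a test.

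For tests, counts were summed per library and class and fitted in edgeR 4.0.16 (R 4.3.3) with TMM scaling, filterByExpr and the robust quasi-likelihood F test, with the library as a block. The spread was shared over the sums of all classes found in every library. P-values are two-sided and adjusted by Benjamini-Hochberg over genes that served neither for clustering nor for naming in any library, with a threshold of 0.05. The standard error is the log2 fold change divided by the square root of F. The p-value sets a class difference against the spread that is left in all class sums of the fit after library and class, over libraries that differ in platform. The stroma fit held 18 class sums with 10 residual degrees of freedom. The early nephron fit held 20 with 11, although only 2 libraries hold that class. The spread therefore comes in large part from classes outside the comparison. Genes are symbols shared by all 3 count tables, 17864 in number. CPM of Gdnf by class are over all counts of the class, CPM of other genes are over the shared genes, and log2 ratios per library in the tests are on the TMM scale of the fit. The 12 gene lists were fixed beforehand and cover the GDNF-RET axis, WNT, FGF, BMP and TGF-beta, Notch, Hedgehog, retinoid, growth factor and guidance signals, basement membrane and adhesion, developmental transcription factors, the cell cycle and dissociation stress. Lists were tested with camera (limma 3.58.1) with the preset and with an estimated correlation, and with fry. List members could not serve as variable genes, while other genes that served for clustering were left out of the tests. The background of camera therefore lacks many of the genes that vary most between cells, which favours calls of the lists. Counts of list members past the threshold are likewise not comparable with the count over all genes tested.

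Genes were named by a rule. Gdnf was always named. From each list up to 2 members with the largest log2 fold change were taken among those past the threshold and changed the same way in each library. Outside the lists the 5 largest rises and the 5 largest falls were taken under the same conditions, with at least 30 summed counts per library over both classes. For genes taken this way, a shared direction in the libraries was set by the rule and is no separate result. In the platform comparison, the 5 genes at each end of the log2 ratio of 1 library to the mean of the other 2 were taken among genes with 50 or more CPM in any library. For genes of other lineages the rule took 2 members per marker list. Some genes that meet the rule, a list count and some markers are not reported here. Other names in the text were chosen after their values were seen. Predicted genes and genes with a large exon overlap with another gene are given as uncertain, the latter with the overlap.

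Platforms were not tested against each other because each has 1 library. Shares and CPM have exact (Clopper-Pearson or Poisson) 95% intervals, a count of 0 is given with an upper limit, and folds against a class with 1 to 3 counts are given as a ratio of summed counts with its exact interval. These intervals cover counting error only, and C1 reads are not independent molecules. The ratios of summed counts pool UMIs and C1 reads, so they need not hold in a single library. UMI cells were also thinned to 4000 UMIs and C1 cells to 50000 reads, which left out shallower cells. Platform list medians were ranked among 10000 random lists matched on expression. Gene positions come from GENCODE vM21. The comparisons, lists, classes and first set of alternatives were fixed before the data were examined. The alternatives were DESeq2 1.42.0, limma, relative log expression scaling, no filter on low counts, no library block, each library left out, stricter cells, other doublet removal, other clustering settings and classes by marker z score. Chosen after seeing the data were the removal of barcodes with over 5 times the median count, the C1 name groups as separate libraries, a stromal zone by z score alone, all nephron epithelium in place of the early class, Gdnf against endothelium, and the tests of the zone comparison beyond its cell and class settings. The edgeR step was tested on simulated data with 8888 genes, where 8.16% of genes changed 1.5-fold, 36.2% changed 2-fold, 85.1% changed 4-fold and 92.0% changed 8-fold were recovered, and 4 of 111 calls were unchanged genes. The simulation gave all classes of a library the same profile apart from the genes changed in stroma, and each gene the same spread on every platform. The real class sums differ more, so the simulation does not give the rate of false calls in these data. Figures were drawn with matplotlib 3.10.9.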

Results

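The data are single-cell transcript counts from wild-type embryonic mouse kidney, in 3 libraries made with Drop-seq, 10x Chromium and Fluidigm C1. At this stage the kidney holds cap mesenchyme (the nephron progenitors), the epithelium that forms from it, the branching ureteric epithelium, stroma, endothelium and immune cells. The filters kept 1964 Drop-seq, 2130 10x and 883 C1 cells. They removed 36 Drop-seq and 43 10x barcodes with too few genes, 105 10x barcodes with a high mitochondrial share, and 17 10x and 11 C1 doublets. Total counts in kept cells were 17751487 UMIs for Drop-seq, 17465306 UMIs for 10x and 171283962 reads for C1. Median counts per cell were 7060 UMIs in Drop-seq, 7369 UMIs in 10x and 166712 reads in C1, with medians of 2666, 2623 and 4595 detected genes. At 4000 UMIs per cell, the medians were 1889 genes in Drop-seq and 1761 in 10x. Mitochondrial genes took a median of 2.62% of counts in Drop-seq and 4.35% in 10x, shares that cover 36 listed genes in Drop-seq and 13 in 10x. Each platform has 1 library, so differences between platforms carry no replicate error and were not tested, and the intervals given for shares and levels cover counting error only.

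All 3 libraries held the main cell classes of the embryonic kidney, in different shares. Cap mesenchyme made up 29.99% of kept cells in Drop-seq (95% interval 28.0 to 32.1%), 11.2% in 10x (9.87 to 12.6%) and 19.3% in C1 (16.7 to 22.0%). Stroma made up 21.3% in Drop-seq (19.5 to 23.2%), 40.1% in 10x (38.05 to 42.3%) and 44.3% in C1 (41.0 to 47.6%). Nephron epithelium of all stages made up 27.5%, 17.3% and 21.5% of cells in Drop-seq, 10x and C1, and ureteric epithelium 8.81%, 7.18% and 5.21%. Endothelium made up 5.19% of Drop-seq cells, 18.2% of 10x cells and 8.27% of C1 cells, and immune cells 0.967%, 1.596% and 1.47%. A podocyte class (4.07%) and an erythroid class (2.14%) were named in Drop-seq alone. A 10x cluster of 78 cells with podocyte transcripts was left unnamed because erythroid markers outnumbered podocyte markers among its top 10 genes. In 10x no cluster was named early nephron epithelium, 94 cells (4.41%) were left unnamed, and 292 stromal cells (13.7%) were given no zone because their top genes held more markers of the other stromal class. The cap mesenchyme share was 22.1% in Drop-seq with classes by marker z score, and in C1 it was 13.5% with no doublet removed and 12.8% without the 5 barcodes of highest count. The C1 stroma share was 28.99% at Leiden resolution 0.6, 29.9% at resolution 1.6 and 25.6% with classes by marker z score, which gave 32.5% in 10x and 18.0% in Drop-seq. At resolution 0.6 the C1 shares were 14.2% for nephron epithelium, 8.72% for ureteric epithelium and 5.10% for immune cells.

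**Figure D1:**
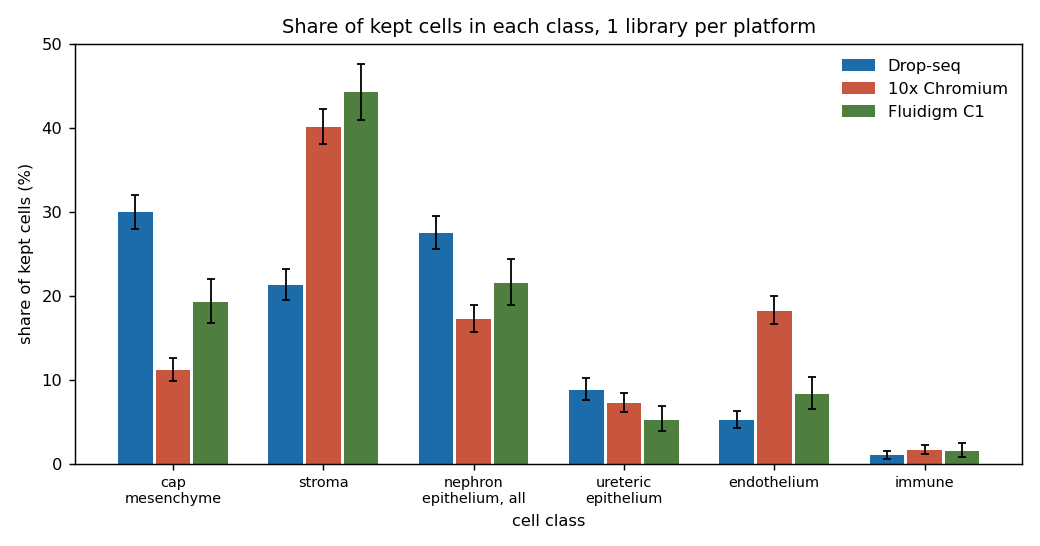
Share of kept cells (%) by cell class on the vertical axis, with bars for Drop-seq, 10x Chromium and Fluidigm C1 and error bars for exact 95% intervals. Cap mesenchyme ranges from 11.2% in 10x to 29.99% in Drop-seq, and stroma from 21.3% in Drop-seq to 44.3% in C1.

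The study asked whether Gdnf, the ligand whose receptor Ret drives branching of the ureteric epithelium, is transcribed in stroma as well as in cap mesenchyme. Gdnf (ENSMUSG00000022144.4) lies on chromosome 15 from 7810846 to 7837575 on the plus strand of the mouse genome, and none of its exonic bases overlap another annotated gene. In stroma, Gdnf reached 52.5 CPM (counts scaled to a common total) in Drop-seq (44.9 to 60.9), 53.2 in 10x (47.5 to 59.5) and 40.03 in C1 (38.5 to 41.6). In cap mesenchyme it reached 27.2 CPM in Drop-seq (22.7 to 32.3), 46.7 in 10x (38.2 to 56.5) and 59.1 in C1 (56.5 to 61.8). Endothelium, a class that should lack the gene, had 2.36 CPM in Drop-seq, 0.273 in 10x and 26.1 in C1. Gdnf was therefore far above the endothelial level in stroma and cap mesenchyme of both UMI libraries, while C1 had Gdnf reads in every class. Across the 3 libraries Gdnf was higher in stroma than in endothelium (log2 fold change 2.91, SE 0.83, edgeR adjusted p = 0.0421) and higher in cap mesenchyme than in endothelium (2.61, SE 0.82, adjusted p = 0.0495), in each of the 3 libraries. The log2 ratios to endothelium in Drop-seq, 10x and C1 were 4.32, 7.07 and 0.55 for stroma and 3.51, 6.95 and 1.14 for cap mesenchyme. Both comparisons with endothelium were chosen after the data were seen, and no alternative setting or left-out library was run for them.

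A Gdnf UMI was found in 25.8% of stromal cells in Drop-seq and in 1.961% of endothelial cells, at median depths of 6494 and 6910.5 UMIs. In 10x the shares were 23.9% of stromal and 0.258% of endothelial cells, at median depths of 6399 and 8571.5 UMIs. The share of cap mesenchyme cells with a Gdnf UMI was 17.5% in Drop-seq and 30.7% in 10x, at median depths of 6773 and 8497 UMIs. At 4000 UMIs per cell, the stromal share was 16.4% in Drop-seq and 15.05% in 10x, and the cap mesenchyme share 9.11% and 17.6%. Endothelial cells at that depth had a share of 0.980% in Drop-seq and 0 of 338 cells in 10x, which allows up to 1.09%. In C1, Gdnf reads were found in 47.6% of cap mesenchyme cells, 30.7% of stromal cells and 26.0% of endothelial cells. At 50000 reads per cell these shares were 39.3%, 27.3% and 13.0%. The intervals of stroma (22.8 to 32.2%) and endothelium (6.14 to 23.3%) overlapped at that depth. Whether the endothelial reads are background or a low true level stays open.

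Gdnf did not differ detectably between stroma and cap mesenchyme, with a log2 fold change of 0.30 (SE 0.70, 95% interval -1.25 to 1.85, adjusted p = 0.900). On the TMM scale of the fit, which differs from the CPM above, the log2 ratio of stroma to cap mesenchyme was 0.82 in Drop-seq, 0.13 in 10x and -0.59 in C1. Without the Drop-seq library the fitted value was -0.02. In the authors' normalized 10x table, where most entries were divided by the total of another cell, the mean of Gdnf gave a log2 ratio of -0.17, against 0.07 from the counts scaled per cell. In C1, the ratio in read CPM differed in sign between the name groups of cells. The HT cells had 31.7 CPM in stroma and 68.9 in cap mesenchyme, and the E14 cells 54.2 and 38.9. The share of cells with Gdnf reads did not reverse. In the HT cells it was 50.8% in cap mesenchyme, above the stromal 95% interval of 24.3 to 36.2%. In the E14 cells it was 40.4% in cap mesenchyme and 31.8% in stroma, with overlapping intervals. These shares were not thinned to equal depth. Cells of the nephrogenic zone were 33 of 240 stromal cells in HT and 81 of 151 in E14. Within the zones Gdnf was at 86.5 CPM in HT and 89.4 in E14 for the nephrogenic zone, and at 24.96 and 25.8 for other stroma, beside 28.3 and 22.9 in endothelium.

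**Figure D2:**
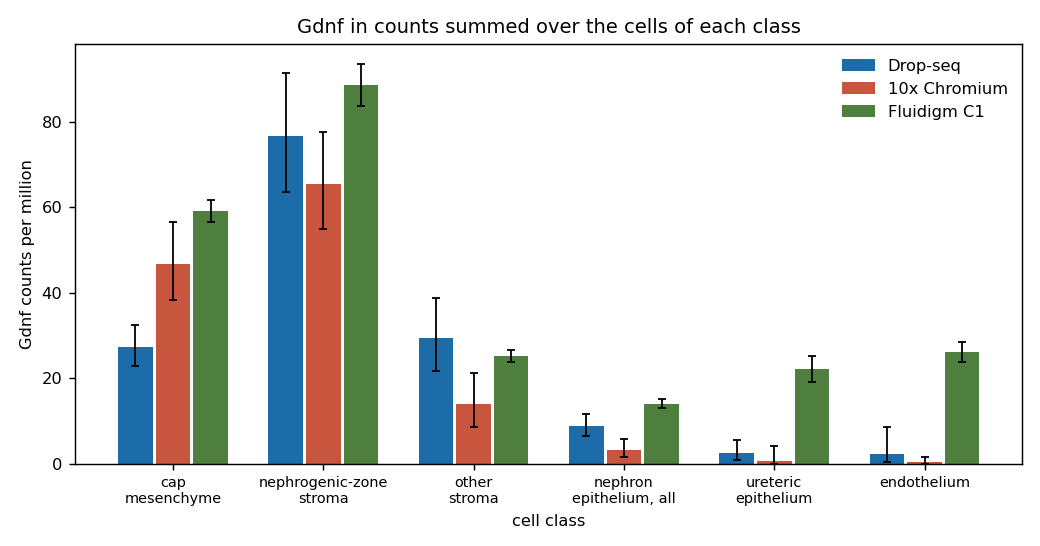
Gdnf level in CPM (vertical axis) by cell class for Drop-seq, 10x Chromium and Fluidigm C1, with exact 95% intervals as error bars. Nephrogenic-zone stroma lies between 65.4 and 88.5 in the 3 libraries and other stroma between 13.8 and 29.3. Endothelium is at 2.36 in Drop-seq, 0.273 in 10x and 26.1 in C1. The 10x stromal cells given no zone are not drawn.

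Among stromal cells given a zone, Gdnf counts were denser in those of the nephrogenic zone, the outer layer where new nephrons form. Gdnf stood at 76.6 CPM in nephrogenic-zone stroma and 29.3 in other stroma of Drop-seq, at 65.4 and 13.8 in 10x, and at 88.5 and 25.2 in C1, where endothelium had 26.1. The fitted log2 fold change was 1.88 (SE 0.69, 95% interval 0.38 to 3.37) and the difference had the same direction in all 3 libraries, but Gdnf did not pass the threshold over all genes tested (edgeR adjusted p = 0.436). Without C1 the log2 fold change was 1.71 (adjusted p = 0.0124). A Gdnf UMI was found in 41.5% of nephrogenic-zone cells in Drop-seq and 29.2% in 10x, and at 4000 UMIs per cell in 26.4% and 19.5%, beside the endothelial shares of 0.980% and 0 of 338 cells. The 10x stromal cells given no zone had 68.1 CPM and held 159 of the 314 stromal Gdnf counts of 10x, but entered neither side of this comparison. Their larger cluster, of 186 cells, had 81.4 CPM, with 1 zone and 3 other-stroma markers among its top 10 genes. A 10x cluster of 68 cells named nephrogenic-zone stroma had 10.1 CPM. The 10x contrast therefore depends on how its clusters were assigned to zones. Other stroma was not uniform in Drop-seq and C1 either. In Drop-seq its cluster of 143 cells had 46.6 CPM (33.9 to 62.6) and its cluster of 93 cells 6.87. In C1 its clusters of 142 and 135 cells had 36.1 and 13.6 CPM. These values lie below the nephrogenic-zone level of the same library, but the size of the contrast depends on which clusters are summed. Of other genes, Angpt1, a ligand of the endothelial receptor Tek, was lower in the nephrogenic zone (-4.37, SE 0.64, adjusted p = 0.00304), and so were the collagen IV chain gene Col4a2 (-1.67, SE 0.18, adjusted p = 2.1e-05), Zeb2 (-2.57, SE 0.40, adjusted p = 0.0132), Sema5a (-2.26, SE 0.41, adjusted p = 0.0225), Rhou (-1.70, SE 0.31, adjusted p = 0.0223) and Bmp4 (-1.95, SE 0.36, adjusted p = 0.0259). A further collagen IV chain gene, Col4a5, was higher (1.87, SE 0.36, adjusted p = 0.0342), as was Mllt4 (1.03, SE 0.18, adjusted p = 0.0178). In total 2 genes were higher and 7 lower of 8839 tested, and the one not yet named, Col4a1, was chosen after its values were seen. Each of the 9 had the same direction in all 3 libraries, which the naming rule required of all but Col4a1. Leaving out a library gave 2 genes without Drop-seq, 5 without 10x and 65 without C1. The number was 0 with no library block, 2 with the C1 name groups apart, 3 with cells of 1000 or more genes, 4 with limma, 5 with classes by marker z score, 15 at Leiden resolution 1.6, 27 at resolution 0.6, 28 with 1000 variable genes and 45 with DESeq2. The call of Col4a2 held in 17 of 18 settings, those of Angpt1 and Sema5a in 11, Bmp4 in 10, Rhou in 8 of 17, Zeb2 in 7, Mllt4 in 6 and Col4a5 in 3. Of the 8 genes of the naming rule, 1 remained past the threshold without Drop-seq, 3 without 10x and 7 without C1, all in the same direction. By camera with the preset correlation the basement membrane list was lower in the nephrogenic zone (adjusted p = 0.000233, and adjusted p = 0.131 with an estimated correlation), the growth factor list was lower (adjusted p = 0.0225, and adjusted p = 0.573 with an estimated correlation) and the cell cycle list was higher (adjusted p = 0.000233, and adjusted p = 0.573 with an estimated correlation).

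Stroma differed from cap mesenchyme in ligands, receptors and matrix genes, a comparison that bears on which class sends and receives each signal. Ecm1, a secreted matrix protein that responds to retinoic acid, was higher in stroma (log2 fold change 4.02, SE 0.35, adjusted p = 7.7e-06), and the retinoic acid receptor gene Rarg was higher (2.43, SE 0.46, adjusted p = 0.00368). Among transcription factors, Ebf1 (4.43, SE 0.83, adjusted p = 0.0101) and Tshz3 (3.40, SE 0.65, adjusted p = 0.00377) were higher in stroma. The ligand Wnt5a (2.60, SE 0.53, adjusted p = 0.00678) and the WNT receptor Fzd1 (2.48, SE 0.39, adjusted p = 0.00144) were higher in stroma, as was the growth factor Igf1 (3.57, SE 0.88, adjusted p = 0.0403). Gfra1, which codes for the co-receptor that binds GDNF and lies on chromosome 19 from 58235604 to 58455909, was lower in stroma (-2.64, SE 0.53, adjusted p = 0.0100), and so were Kif26b, which acts in the adhesion of cap mesenchyme (-1.86, SE 0.50, adjusted p = 0.0313), and the ligand Fgf9 (-2.24, SE 0.63, adjusted p = 0.0409). The fibrillar collagen gene Col5a2 (3.60, SE 0.62) and the microfibrillar collagen gene Col6a1 (3.54, SE 0.54) were higher in stroma. Each of these genes had the same direction in all 3 libraries, which the naming rule required. Outside the lists, the rises in stroma included St8sia1 (3.97, SE 0.77), Lrrc32 (3.92, SE 0.93), Rerg (3.75, SE 1.05) and Naalad2 (3.75, SE 0.98), and the falls Nell1 (-3.22, SE 0.59), Lrp8 (-3.07, SE 0.66), Gldc (-2.98, SE 0.72), Kazald1 (-2.83, SE 0.72) and Sel1l3 (-2.73, SE 0.69). Aim2 had 473 counts in stroma and 1 in cap mesenchyme, a ratio of 268 per total count (95% counting interval 47.8 to 10589.5). These counts pool UMIs and C1 reads, so the ratio need not hold in a single library. The call of Aim2 held in 11 of 15 settings.

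In all, 234 genes were higher and 266 lower in stroma of 9111 tested (edgeR quasi-likelihood, Benjamini-Hochberg). The number past the threshold was 18 without Drop-seq, 92 without 10x and 1271 without C1. Of the 31 genes the naming rule gave besides Gdnf, 2 of 31 remained past the threshold without Drop-seq, 8 of 31 without 10x and 28 of the 29 tested without C1, all in the same direction. The number was 912 at Leiden resolution 0.6, 846 with 1000 variable genes, 279 with classes by marker z score and 2 with no library block.

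**Figure D3:**
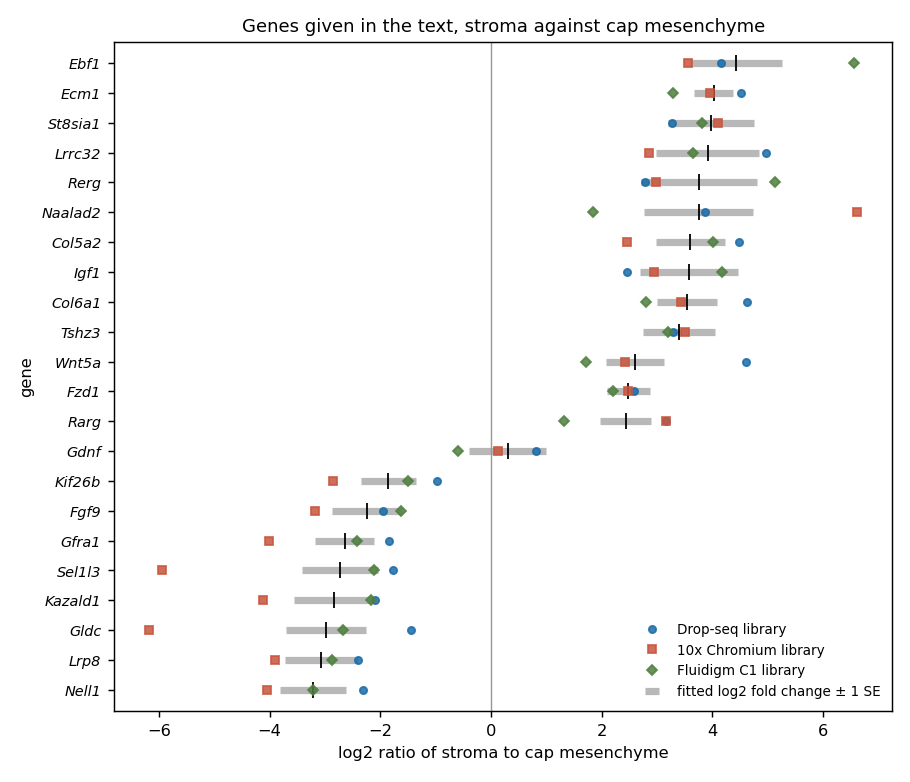
Log2 fold change of stroma against cap mesenchyme (horizontal axis) for genes whose fitted value is given in the text, with a point per library for the ratio of TMM-scaled CPM and a bar for the fitted value with 1 SE. Ebf1 is fitted at 4.43 and Ecm1 at 4.02, and Gfra1 at -2.64.

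The fixed lists gave the following counts in stroma against cap mesenchyme, first over all genes tested and then adjusted over the list alone, with members beyond the naming rule chosen after their values were seen. Of 16 retinoid genes 5 rose (Ecm1, Rarg, Rarb, Rxra and Dhrs3), and 8 rose adjusted over the list alone. Of 53 growth factor and guidance genes 18 rose and 5 fell (Pdgfc, Cxcr4, Met, Ntf3 and Efna1), and 27 rose and 7 fell adjusted over the list alone. Of 41 basement membrane and adhesion genes 13 rose and 2 fell (Lama5 and Itga6), and 16 rose and 2 fell adjusted over the list alone. Of 27 BMP and TGF-beta genes 6 rose and 2 fell (Bmp7 and Acvr2b), and 15 rose and 2 fell adjusted over the list alone. Of 40 transcription factors 11 rose and 5 fell (Tcf4, Sox11, Myc, Hmga2 and Foxp1), and 15 rose and 7 fell adjusted over the list alone. Of 30 WNT genes 3 rose (Wnt5a, Fzd1 and Nkd1) and 1 fell (Fzd4), and 7 rose and 3 fell (Fzd4, Rspo1 and Rspo3) adjusted over the list alone. Of 30 GDNF-RET genes 3 fell (Gfra1, Kif26b and Etv4), and 6 fell adjusted over the list alone. Of 13 Notch genes 2 rose (Maml2 and Notch1) and 1 fell (Hes1), with the same genes adjusted over the list alone. In the Hedgehog list of 9 genes 1 rose (Boc), and 2 rose (Boc and Gli2) and 1 fell (Gas1) adjusted over the list alone. Of 13 FGF genes 1 fell (Fgf9), and 2 rose (Fgf12 and Fgfr3) and 4 fell (Fgf1, Fgf9, Fgf10 and Fgf20) adjusted over the list alone. Of 26 stress genes 3 rose (Atf3, Klf6 and Hspb1), and 4 rose (with Klf4) adjusted over the list alone. In the cell cycle list of 30 genes 1 fell (Mcm7), also adjusted over the list alone.

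As sets, 4 lists were higher in stroma by camera with an estimated correlation: the retinoid, growth factor and basement membrane lists (adjusted p = 0.00438 each) and the BMP and TGF-beta list (adjusted p = 0.00451). Calls with the preset correlation alone were the transcription factors, higher (adjusted p = 0.000964, and adjusted p = 0.164 with an estimated correlation), the WNT list, higher, and the GDNF-RET list, lower (adjusted p = 0.0244 each, and adjusted p = 0.423 with an estimated correlation), the Notch list, higher (adjusted p = 0.0244, and adjusted p = 0.238 with an estimated correlation), the Hedgehog list, higher (adjusted p = 0.0301, and adjusted p = 0.238 with an estimated correlation) and the stress list, higher (adjusted p = 0.0148, and adjusted p = 0.222 with an estimated correlation). The cell cycle list (adjusted p = 0.188) and the FGF list (adjusted p = 0.756) did not pass, and the FGF list had a median log2 fold change of -0.09, a mean of 0.10 and a test direction down. In the other comparisons the calls that held with an estimated correlation were the basement membrane list in ureteric epithelium, and the basement membrane and Notch lists in early and in all nephron epithelium. In every comparison a background without the variable genes favours such calls, so they do not show that a list exceeds genes at large.

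Ureteric epithelium is the branching duct that responds to GDNF. Ret, which codes for the GDNF receptor and lies on chromosome 6 from 118151745 to 118197718, was higher there than in cap mesenchyme (log2 fold change 6.35, SE 0.51, adjusted p = 2.4e-07), at 86.8 CPM in Drop-seq, 134 in 10x and 201 in C1. The claudin genes Cldn3 (6.92, SE 0.39, adjusted p = 1.7e-08) and Cldn4 (6.44, SE 0.48, adjusted p = 1.8e-07) and the ligand gene Kitl (3.93, SE 0.31, adjusted p = 1.7e-07) were higher as well. Gdnf was lower in ureteric epithelium (-2.77, SE 0.82, 95% interval -4.59 to -0.95, adjusted p = 0.0462), with log2 ratios on the same TMM scale of -3.65 in Drop-seq, -5.98 in 10x and -1.41 in C1. The 10x ratio rests on 1 Gdnf count in ureteric epithelium and the Drop-seq ratio on 5, so their sizes are uncertain. The Gdnf call did not hold without Drop-seq (-2.61, adjusted p = 0.423) or without 10x (-1.95, adjusted p = 0.0968), and without C1 the log2 fold change was -4.44 (adjusted p = 1.6e-08). The call held in 8 of 17 settings, and the log2 fold change ranged from -4.44 to -1.95 over them. The ligand Fgf10 (-5.05, SE 0.94, adjusted p = 0.00159) and Gas1, a Hedgehog and GDNF co-receptor gene (-3.35, SE 0.59, adjusted p = 0.00436), were lower, and 19.9% of the exonic bases of Gas1 overlap an antisense gene, which makes its value uncertain. Of the retinoid enzymes, Aldh1a3 was higher (5.91, SE 0.65), and Aldh1a1 had 262 counts in ureteric epithelium and 3 in cap mesenchyme, a ratio of 273 per total count (95% counting interval 92.2 to 1330.2). The Aldh1a1 counts pool UMIs and C1 reads. Tbx3 (5.08, SE 0.59) and Tfap2a (6.19, SE 0.87) were higher among transcription factors. Outside the lists, St14 (6.39, SE 0.59) and Ocln (5.99, SE 0.62) were among the rises and Lbx2 (-5.89, SE 0.61) and Chst2 (-5.65, SE 0.53) among the falls. Each of these genes had the same direction in all 3 libraries, which the naming rule required of all but Gdnf.

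In ureteric epithelium 563 genes were higher and 502 lower of 9111 tested. The number past the threshold was 162 without Drop-seq, 434 without 10x and 1730 without C1, and it was 618 with classes by marker z score and 194 with no library block. Of the 34 named genes, 18 of 34 remained past the threshold without Drop-seq, 24 of 34 without 10x and 32 of the 32 tested without C1, all in the same direction. Of 41 basement membrane and adhesion genes 20 rose and 5 fell (Nid1, Vcan, Itga9, Cdh2 and Cdh11), also adjusted over the list alone, and this list was higher with an estimated correlation (camera adjusted p = 0.00901). Of 30 GDNF-RET genes 8 rose and 12 fell, and 12 rose and 13 fell adjusted over the list alone, with a median log2 fold change of -0.19, a mean of -0.29 and a test direction up (adjusted p = 0.424). The Notch list had a median of -0.10, a mean of -0.05 and a test direction up (adjusted p = 0.246). Of 26 stress genes 8 rose, and 8 rose and 1 fell (Hspa8) adjusted over the list alone (camera adjusted p = 0.00388, and adjusted p = 0.218 with an estimated correlation). Of 53 growth factor genes 7 rose and 3 fell (Pdgfc, Ntf3 and Efnb1), and 9 rose and 4 fell (with Ngfr) adjusted over the list alone (camera adjusted p = 0.00906, and adjusted p = 0.249 with an estimated correlation). Of the 218 members of the 12 fixed lists with enough counts, 132 had their highest class in common in all 3 libraries (60.6%, against 3.61% if the libraries were independent), among them 18 of 21 GDNF-RET genes, 6 of 29 cell cycle genes and 5 of 17 stress genes.

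**Figure D4:**
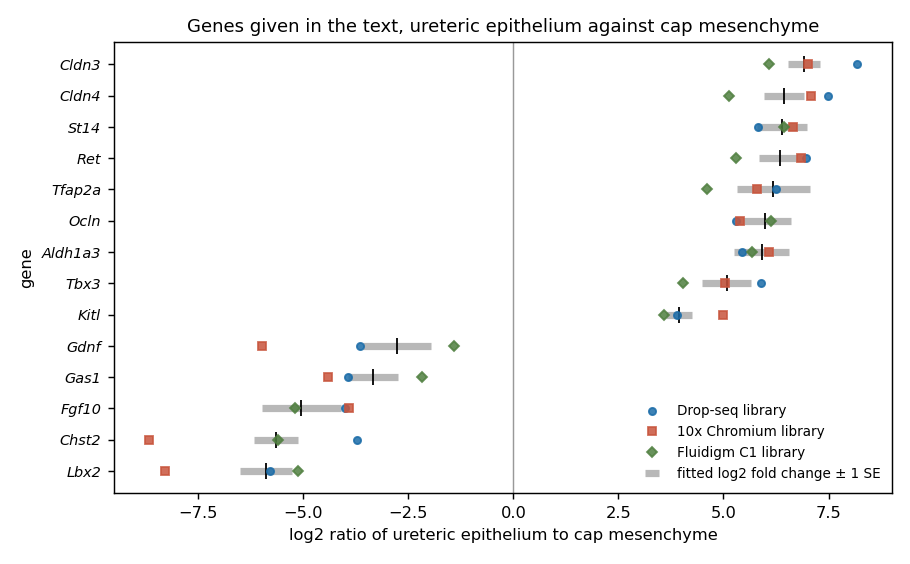
Log2 fold change of ureteric epithelium against cap mesenchyme (horizontal axis) for genes whose fitted value is given in the text, with a point per library for the ratio of TMM-scaled CPM and a bar for the fitted value with 1 SE. Ret is fitted at 6.35 and Gdnf at -2.77.

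Early nephron epithelium is the first epithelium formed from cap mesenchyme. In it the WNT co-receptor gene Lgr5 was higher (log2 fold change 3.95, SE 0.62, adjusted p = 0.00139), and so were the ligand genes Bmp2 (3.03, SE 0.57, adjusted p = 0.0106) and Bmp4 (2.26, SE 0.37, adjusted p = 0.00184). The cadherin gene Cdh1, which holds epithelial cells together (3.33, SE 0.67, adjusted p = 0.0327), and the ephrin receptor gene Epha4 (2.78, SE 0.33, adjusted p = 7.8e-05) were higher. Nrarp, a Notch target, was higher (3.91, SE 0.38, adjusted p = 4.8e-06), but 79.4% of its exonic bases overlap an antisense gene, which makes it uncertain. The falls were Foxd2 (-3.14, SE 0.61), Nell1 (-2.95, SE 0.69), Tmtc2 (-2.86, SE 0.54), Scx (-2.45, SE 0.55) and Sfxn3 (-2.34, SE 0.55) among genes outside the lists. Both libraries that held the class, Drop-seq and C1, gave the same direction for each of these genes, which the naming rule required. Gdnf did not pass the threshold (-1.95, SE 0.89, adjusted p = 0.485). Fgf15 had 340 counts in early nephron epithelium and 2 in cap mesenchyme, a ratio of 284 per total count (95% counting interval 78.1 to 2357), with 25.7% of its exonic bases under an antisense gene. These counts pool Drop-seq UMIs and C1 reads, so the ratio need not hold in either library alone. The call of Fgf15 held in 5 of 12 settings. In total 82 genes were higher and 18 lower of 9432 tested, and the number was 72 without 10x, where 14 of the 24 named genes remained past the threshold. The number ranged from 2 with no library block to 284 with 1000 variable genes, and was 244 with no doublet removed, 221 without barcodes of highest count, 204 with DESeq2, 183 at Leiden resolution 1.6, 171 with cells of 1000 or more genes, 59 at Leiden resolution 0.6, 43 with limma and 41 with the C1 name groups apart. Of 42 basement membrane genes 12 rose, and 17 rose and 2 fell (Itga9 and Cdh11) adjusted over the list alone (camera adjusted p = 0.00176 with an estimated correlation), and of 14 Notch genes 3 rose (Nrarp, Lfng and Notch1), and 4 rose (with Maml2) adjusted over the list alone (adjusted p = 0.00952 with an estimated correlation). Of 28 BMP and TGF-beta genes 4 rose (Bmp2, Bmp4, Fstl1 and Id4), and 6 rose and 1 fell (Tgfbr2) adjusted over the list alone (camera adjusted p = 0.0013, and adjusted p = 0.0974 with an estimated correlation). Of 31 WNT genes 2 rose (Lgr5 and Lgr4), and 4 rose (with Fzd6 and Fzd10) and 1 fell (Rspo3) adjusted over the list alone (camera adjusted p = 0.0116, and adjusted p = 0.576 with an estimated correlation). In the cell cycle list 1 gene rose (Cenpa), and 5 rose (with Ccnb1, Plk1, Ube2c and Rrm2) adjusted over the list alone (camera adjusted p = 0.0013, and adjusted p = 0.576 with an estimated correlation).

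All nephron epithelium, a sum of the early, proximal and distal classes chosen after the data were seen because 10x had no early class, could be set against cap mesenchyme in all 3 libraries. The FGF receptor gene Fgfr4 (4.01, SE 0.66, adjusted p = 0.0014) and the metallothionein gene Mt1 (4.65, SE 0.57, adjusted p = 0.0014) were higher. Robo2, a receptor that restricts where Gdnf is made, was lower (-3.48, SE 0.70, adjusted p = 0.0215), and so was Fgf20, a ligand that maintains progenitors (-3.69, SE 0.79, adjusted p = 0.0097). Each of the 4 had the same direction in all 3 libraries, which the naming rule required. Gdnf did not pass the threshold (-2.48, SE 0.87, adjusted p = 0.144), and without C1 it did (-2.51, adjusted p = 0.00273). In total 401 genes were higher and 221 lower of 9199 tested, and the number was 89 without Drop-seq, 223 without 10x and 991 without C1. With classes by marker z score 138 were higher and 53 lower, and with no library block 63 and 10. Of the 33 named genes, 10 of the 32 tested remained past the threshold without Drop-seq, 22 of 33 without 10x and 29 of the 32 tested without C1, all in the same direction. Of 42 basement membrane genes 18 rose and 2 fell (Itga9 and Cdh11), and 21 rose and 5 fell adjusted over the list alone (camera adjusted p = 0.0300 with an estimated correlation), and of 14 Notch genes 4 rose (Nrarp, Lfng, Notch1 and Maml2), also adjusted over the list alone (adjusted p = 0.0432 with an estimated correlation). Of 31 GDNF-RET genes 2 rose (Npnt and Frem2) and 6 fell, and 4 rose and 14 fell adjusted over the list alone (camera adjusted p = 0.00617, and adjusted p = 0.537 with an estimated correlation).

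The study also asked whether nephron progenitors carry transcripts of later lineages. Wfdc2, a secreted protein of the ureteric epithelium, was found in 16.6% of cap mesenchyme cells and 1.961% of endothelial cells in Drop-seq, and in 15.3% and 3.55% in 10x, with all cells thinned to 4000 UMIs. In C1, thinned to 50000 reads, Wfdc2 was found in 49.4% of cap mesenchyme and 47.8% of endothelial cells. Cdkn1c, a cell cycle inhibitor gene on the podocyte list, was found in 76.0% of cap mesenchyme and 49.0% of endothelial cells in Drop-seq, 83.8% and 60.1% in 10x, and 95.2% and 81.2% in C1. Without thinning, it was in 93.6% of a 10x cluster of 78 cells with podocyte transcripts and in 87.1% of other 10x cells. Its share in cap mesenchyme is therefore not particular to a podocyte lineage. The stromal transcription factor gene Tcf21 was found in 42.4% of cap mesenchyme and 7.84% of endothelial cells in Drop-seq and in 67.9% and 39.1% in C1, while in 10x it was in 1.85% of cap mesenchyme cells and 0 of 338 endothelial cells, which allows up to 1.09%. In stroma, Tcf21 was found in 5.19% of 10x cells, against 59.8% in Drop-seq and 81.9% in C1, so its low share in 10x is not particular to progenitors. Crabp1, a retinoid-binding protein of nephrogenic-zone stroma, was in 7.01% of cap mesenchyme and 0 of 102 endothelial cells in Drop-seq (up to 3.55%) and in 7.87% and 1.48% in 10x. For the proximal tubule gene Fxyd2 and the distal nephron gene Hoxd8 the cap mesenchyme share had an interval that overlapped the endothelial interval in all 3 libraries. Shares with intervals wholly above endothelium were found for 5 of 100 marker genes in Drop-seq (Cdkn1c, Wfdc2, Crabp1, Tcf21 and Tnc), 15 of 101 in 10x and 3 of 100 in C1 (Cdkn1c, Tcf21 and Tnc), and shares wholly below for 6, 3 (Podxl, Mecom and Mcam) and 8. Tnc, Podxl and Mcam were chosen after their values were seen. Of the 15 in 10x, 6 are markers of nephrogenic-zone stroma and 7 of other stroma. Without thinning the numbers above endothelium were 5, 21 and 2, and in Drop-seq the number was 3 with cells of 1000 or more genes and 3 without barcodes of highest count.

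Levels of the same class differed between platforms by large ratios for single genes of several kinds. Values of genes in near-identical families, such as histone and haemoglobin genes, are uncertain because reads cannot be assigned to 1 member with certainty. In cap mesenchyme, the ribosomal protein gene Rpl26 had 2367 CPM in Drop-seq, 3826 in 10x and was listed at 0 in C1. Gstp2, a glutathione transferase gene, had 597 CPM in Drop-seq, 908 in C1 and was listed at 0 in 10x. Of the 31-base words sampled from their transcripts, Rpl26 shares 55% and Gstp2 80% with other annotated genes, so both values of 0 are uncertain. Sox11, a developmental transcription factor gene, had 13.2 CPM in Drop-seq, 455 in 10x and 524 in C1 (a log2 ratio of -5.10 for Drop-seq against the mean of the others), and the ubiquitin-conjugating enzyme gene Ube2s had 2.80, 584 and 3.57 (7.13 for 10x). The haemoglobin gene Hba-a2 had 1327 CPM in Drop-seq and 1.43 in 10x and was listed at 0 in C1, and the predicted gene Gm5148 had 1419 in C1 and 13.0 in Drop-seq and was listed at 0 in 10x, both uncertain. Across genes, which are not independent replicates, cap mesenchyme levels of Drop-seq and 10x correlated with r = 0.769 and rho = 0.760 over 4194 genes, those of Drop-seq and C1 with r = 0.622 and rho = 0.670, and those of 10x and C1 with r = 0.647 and rho = 0.673. For stroma the r values were 0.766, 0.628 and 0.670 over 4320 genes. Among the lists, cell cycle genes had a median log2 ratio of -0.96 in 10x cap mesenchyme, below all 10000 matched random lists, and transcription factors had a median of -0.70 in C1, also below all of them. Stress response genes had a median of 1.18 in C1 cap mesenchyme, at percentile 99.96 of the matched lists, and of 0.17 in C1 stroma, at percentile 52.8. The random lists were matched on expression, not on how members vary together. Cell cycle genes did vary together (estimated correlation 0.437 in the stroma comparison), which makes an extreme percentile more likely. With 1 library per platform the percentiles are no test of a platform difference.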

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

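The tests of doublets (marker excess and thinned shares), of free RNA and of even carry-over of reads were chosen only after the results they concern were seen, and the tests of plate columns and rows before.

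The Gdnf ratio of stroma to cap mesenchyme differed in sign between platforms and, in read CPM, inside the C1 library. On the TMM scale of the fit its log2 value was 0.82 in Drop-seq, 0.13 in 10x and -0.59 in C1, and with 1 library per platform the difference was not tested. Inside C1 the HT cells had 31.7 CPM in stroma and 68.9 in cap mesenchyme and the E14 cells 54.2 and 38.9. Endothelium had 28.3 and 22.9, and 33 of 240 and 81 of 151 stromal cells were in the nephrogenic zone. These read CPM carry no spread between cells. In E14 cap mesenchyme the 425 Gdnf reads came from 21 of 52 cells, with up to 135 in 1 cell. Whether the sign follows the platform alone can therefore not be told from them. By share of cells with Gdnf reads, cap mesenchyme was higher in both name groups, with 40.4% against 31.8% and overlapping intervals in E14. These shares were not thinned to equal depth. No biological explanation was tested, since the libraries come from the same tissue and stage, and a difference between the dissected kidneys stays open.

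Gdnf UMIs in stromal cells of the droplet libraries could come from free RNA, or from doublets with cap mesenchyme cells, in which stromal cells with Gdnf would carry an excess of cap mesenchyme markers of 25% or more of the cap mesenchyme level. In 10x the excess was -1.42% (95% interval -3.12 to 0.416%), which argues against doublets. In Drop-seq the share of stromal cells with Gdnf at 4000 UMIs had a lower bound of 12.96%, above the upper bound of 11.8% in cap mesenchyme, which argues against doublets as the whole cause, but the excess was 13.7% (1.44 to 26.7%) and its interval reaches the bound, so doublets in part of the cells cannot be told apart from stromal transcription. The share of endothelial cells with Gdnf had an upper bound of 1.43% in 10x and 6.90% in Drop-seq, below the lower bounds of 21.0% and 21.7% in stroma, which argues against free RNA in both libraries. Transcription of Gdnf in stromal cells remains a hypothesis, found and tested on the same cells.

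Gdnf reads in every class of the C1 library, endothelium included, could come from reads shared between cells of a plate column or row, or carried over evenly from all cells. Endothelial marker reads in cells named otherwise did not follow the endothelial reads of their column (rho = 0.0236 over 38 columns, permutation p = 0.890) or of their row (rho = 0.00395 over 73 rows, permutation p = 0.971), but the spread of rho over so few columns and rows is too wide to exclude a weak trend. The endothelial level of Gdnf was 0.765 of the level over all cells, against a median of 0.446 and a 95th percentile of 0.740 over 86 other genes that both droplet libraries show in cap mesenchyme or stroma and not in endothelium. That lies above the bound, but with Gdnf reads in 19 of 73 endothelial cells its spread reaches down to 0.483, so even carry-over cannot be told apart from a low true level, and both stay open.

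Among the 10x cells that entered no comparison, 1 cluster of 78 cells had podocyte transcripts. Nphs1 was found in 21.8% of its cells (95% interval 13.2 to 32.6%), against 0.0975% of other 10x cells and a floor of 3 cells in 78 (3.85%). Wt1 was found in 96.2% of its cells and 23.3% of others, and Podxl in 37.2% and 9.89%. These 3 genes were chosen after their values were seen. The cluster was left unnamed because the erythroid class had 2 markers among its top 10 genes (Hbb-bs and Hba-a1) and the podocyte class 1. No cause was tested.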

How the results depend on the processing

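The removal of barcodes of highest count, the C1 name groups as separate libraries, the stromal zone by z score alone, all nephron epithelium and the further tests of the zone comparison were chosen only after the results were seen. Across platforms no paired analysis was possible because each platform has 1 library and replicate number 1 pairs no samples. Classes were compared within each library, with the library as a block, and the counts with no library block are given below.

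The count of genes past the threshold in stroma moved to 912 at Leiden resolution 0.6, 846 with 1000 variable genes, 279 with classes by marker z score and 2 with no library block, and ranged from 18 to 1271 over the left-out libraries. In ureteric epithelium it moved to 618 with classes by marker z score and 194 with no library block, and ranged from 162 to 1730 over the left-out libraries. In early nephron epithelium it moved to 171 with cells of 1000 or more genes, 244 with no doublet removed, 59 at Leiden resolution 0.6, 183 at resolution 1.6, 284 with 1000 variable genes, 221 without barcodes of highest count, 204 with DESeq2, 43 with limma, 2 with no library block, 41 with the C1 name groups apart and 622 with all nephron epithelium, which changes the class, brings in the 10x library and fits 15 class sums in place of 20. Between the stromal zones it ranged from 0 with no library block to 65 without C1. In early nephron epithelium it was 72 without 10x, and without Drop-seq or C1 this comparison was not run, since 1 library would hold both classes. The classes of 10x gained an early class under several of these settings, so that 3 libraries entered in place of 2 with cells of 1000 or more genes, no doublet removed, resolution 1.6, 1000 variable genes and no barcodes of highest count. Leaving out a library leaves fewer samples, and beyond these constructions the cause was not tested.

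Gdnf in stroma against cap mesenchyme reversed to -0.0168 without Drop-seq, with a range of -0.0168 to 0.50 over the left-out libraries, and stayed short of the threshold in each of the 17 settings. Gdnf in nephrogenic-zone against other stroma passed the threshold without C1 (1.71, adjusted p = 0.0124) and in no other of 18 settings, with a range of 1.65 to 2.21 over the left-out libraries. The cause was not tested.

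The cap mesenchyme share moved to 22.1% in Drop-seq with classes by marker z score, and in C1 to 13.5% with no doublet removed and 12.8% without barcodes of highest count. The stroma share in C1 moved to 40.6% with no doublet removed, 28.99% at Leiden resolution 0.6, 29.9% at resolution 1.6 and 25.6% by z score, and by z score to 32.5% in 10x (35.9% at resolution 1.6) and 18.0% in Drop-seq. Nephron epithelium moved in C1 to 18.8% with no doublet removed, 14.2% at resolution 0.6 and 16.5% without barcodes of highest count, and in Drop-seq to 31.7% at resolution 0.6 and 24.9% without those barcodes. Ureteric epithelium in C1 moved to 8.39% with no doublet removed and 8.72% at resolution 0.6. Immune cells in C1 moved to 5.10% at resolution 0.6 and 5.47% without barcodes of highest count, and in Drop-seq no immune class was named with cells of 1000 or more genes or at resolution 0.6. The number of later-lineage genes above endothelium in Drop-seq moved to 3 with cells of 1000 or more genes and to 3 without barcodes of highest count. The correlation of cap mesenchyme levels moved to 0.738 (Drop-seq and 10x) and 0.622 (10x and C1) without mitochondrial, ribosomal and haemoglobin genes, and with a minimum of 10 CPM to 0.843 (Drop-seq and 10x), 0.763 (Drop-seq and C1) and 0.754 (10x and C1). The cause was not tested.

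Named genes other than Gdnf kept their direction under all alternatives run. The naming rule took only genes changed the same way in each library, which favours this result. In the 3 planned comparisons 1125 values stayed on their side of the threshold and 328 fell short of it, and in the other 2 comparisons 531 stayed, 176 fell short and 1 passed it. Of the summary values 214 stayed, 78 moved, 1 reversed and 1 passed the threshold. Depth limits the C1 shares, where reads are not molecules, and the droplet shares, where 4000 UMIs per cell left 1889 and 1761 genes in the median cell.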

Other observations

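The tests of shared sequence and of the splits for all nephron epithelium and the stromal zones were chosen only after the result was seen, and the tests of transcript length and of the splits for stroma and ureteric epithelium before.

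The genes that differ most between libraries could owe this to transcript length, if C1 reads cover whole transcripts, or to sequence shared with other annotated genes. Across genes, which are not independent replicates, the C1 level relative to the droplet libraries did not rise with exonic length (rho = -0.0273 in cap mesenchyme and -0.0597 in stroma, over 4084 and 4203 genes), which argues against length. Of the genes near 0 in 10x and at 50 or more CPM in both others, 8 of 9 shared 50% or more of their sampled sequence words with another gene (88.9%, 95% interval 51.8 to 99.7%), against 3.29% of 2250 genes with 50 or more in all 3, consistent with reads of shared sequence being left uncounted. Of the genes near 0 in C1, 8 of 18 did (44.4%, 21.5 to 69.2%), so shared sequence cannot be told apart from other causes there. Among the 9 genes near 0 in 10x are the histone genes Hist1h2ac, Hist1h2ad, Hist1h2ah and Hist1h2an and the pair Dynlt1a and Dynlt1b. Members of a family are not independent, so the interval for the 9 is too narrow. No biological explanation was tested.

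The number of genes past the threshold was also counted for the 10 splits of the 6 class sums of each comparison, of which 1 is the real one, too few for a share under 0.05. Of the 10, 4 hold 1 sum per library and the other 6 break the library block. The real split gave 500 genes for stroma and the highest other 0, 1065 and 0 for ureteric epithelium, 622 and 0 for all nephron epithelium, and 9 and 1 for the stromal zones, where the highest other with 1 sum per library gave 0. Every other split mixes both classes, so the class difference enters the spread and lowers the count. The classes were also found by clustering the same cells. The low counts of the other splits therefore cannot decide on chance.

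Some clusters of 10x and C1 carried mixed markers. The 10x cluster named distal nephron with 90 cells had 3 distal and 2 early nephron markers among its top 10 genes, and the proximal tubule cluster with 185 cells had 2 proximal and 2 early nephron markers. The 10x cluster of 68 cells named nephrogenic-zone stroma, which entered the zone comparison, had 3 zone and 3 other-stroma markers. The cap mesenchyme cluster of 105 cells in 10x had 4 own and 2 erythroid markers. In C1 the cap mesenchyme cluster of 52 cells had 2 own and 2 erythroid markers, and the distal nephron cluster of 32 cells 2 own and 2 ureteric markers. Class profiles of each platform had their highest correlation with the same class of the other platforms in all 18 comparisons. The lead was small for distal nephron in C1, with rho = 0.242 against 0.212 for the next class (Drop-seq) and 0.243 against 0.181 (10x), beside 0.697 against 0.0525 for cap mesenchyme between Drop-seq and 10x.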
